A study of Mus musculus with 12 samples.

How the data were processed

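RNA of islets captured by laser from pancreas sections of 6 NOD and 6 NOD.B10 mice, all female and 12 weeks old per the labels, was amplified and labelled with Cy5. A common mouse reference RNA was labelled with Cy3 and hybridised with it on 2-colour Agilent mouse arrays, 1 array per mouse. The dyes were not swapped. The arrays lay on 4 slides and were read on 2 scan days, slide 4 apart from the others. Replicate numbers do not pair the mice of the strains.

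Scanner intensity values (median signal and median local background of either channel, in scanner units) were deposited per array, extracted with Feature Extraction 10.5.1.1 per the file headers, with no normalisation. The same files hold processed intensity values and the log10 ratio of processed Cy5 to Cy3, made by the authors' feature extraction with background subtraction, detrending and dye normalisation per the file headers. That ratio is 0 where neither channel was usable. The deposited series table holds the log2 of processed Cy5 over processed Cy3 without further centring, as its values, equal for 100% of those compared, showed. The labels do not state this. It has 41252 lines, of which 41174 match a non-control probe, and the medians per array run from -0.062 to -0.285. Other deposited columns are quality marks, among them whether a signal is well above background and whether a spot is a feature outlier, as the scanner set them per the file headers. Each array has 45018 spots, of which 1639 are controls, and 41174 non-control probes. No spot was saturated. Spots marked as outliers numbered 160 to 250 per array and were left out of the probe average where another spot of the probe remained.

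Signals were corrected with normexp (offset 50) and loess within each array in limma 3.58.1 under R 4.3.3, and spots of the same probe were averaged. The files hold median but no mean signals per spot, so median signals were used where means had been planned. Probe accessions were matched to gene symbols of a reference annotation of mouse assembly GRCm38.p6, which gave 24375 probes a symbol (17016 symbols) and left 16799 without. The arrays' own coordinates were not used here. A probe was tested when Cy5 was well above background on at least 4 of the 12 arrays, which 5347 probes passed. For each symbol the probe with the highest mean Cy5 signal was taken, which gave 3920 genes. The 1075 passing probes without a symbol, of which 272 were called higher and 113 lower, are not described further. Array data carry no counts, so the number of arrays and the signal over background limit the precision.

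Strains were compared with limma's moderated test (lmFit and eBayes) on the log2 ratios, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Changes are NOD minus NOD.B10, and a fold is 2 to the power of this difference. A gene called higher whose Cy5 signal was well above background on no NOD.B10 array is given as a lower bound, or without a fold where that bound is not above 1. For this bound, its Cy5 signal after normalisation was set, on each NOD.B10 array, at no less than the 10th percentile of signals well above background there. This floor was chosen after the values were seen, since the lowest such signal lay under the median of all probes on 8 of the 12 arrays. It gives a bound above 1 for 519 genes, against 883 with the lowest signal. Genes called lower with no NOD.B10 array well above background are given no fold, nor are genes called higher with 1 such array. A total of 34 gene lists (709 entries, 704 with a current symbol) was fixed for islet cell types and functions, other cell types of the pancreas, leukocytes and immune functions, metabolism, stress and the MHC region. The 30 lists with at least 3 tested members were tested with fry, whose PValue tests whether a list's genes move, on balance, one way. Neither this nor its mixed form compares a list with other genes. Lists were also tested with camera, with an estimated correlation and with a preset one of 0.01, and with an exact 2-sided permutation test over all assignments of the 12 arrays, whose smallest p is 0.00216. With a preset correlation 19 lists passed and with an estimated one 0 (7 at an unadjusted p under 0.05, 6 higher and 1 lower). The permutation test passed 21. Adjusted p values of list means are those of fry, over the lists, and those of genes are limma's.

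The genes named are the 10 largest rises and 10 largest falls among called genes whose fold keeps its sign when any mouse is left out, with unnamed clones passed over. To these come up to 4 members with the smallest p among those passing in each list, or up to 2 where none passes. Ins1, Ins2, Gcg, Sst, Ppy, Iapp, Adora1, Ptprc, Cd3e, Cd79a, H2-Ab1 and H2-K1 are named whatever their values. A few genes that the rule names are not reported here. The tests, lists, naming rule and a first set of alternatives were chosen before the data were examined.

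These alternatives were array weights, the share of spots well above background as a covariate, the acinar mean as a covariate, no background correction, offset 16 and the scanner's processed ratios centred on their medians. Further ones were the authors' table, median centring without loess, Aquantile after loess, Cy5 alone with quantile normalisation, no filter, a filter on all 12 arrays or on both channels, every probe on its own or averaged by gene, and eBayes with trend and robust fitting. Slide as a random block, scan day as a fixed term, a block by replicate number and leaving out each mouse completed them. Values of genes and lists under another scaling are given relative to the shift in the median change of all genes, while their tests are those of the unshifted values. After the data had been seen, 7 more were added: slide as a fixed term, slides 2 and 3 with slide fixed, slide 2 alone, slide 3 alone, without slide 4, leaving out genes with Cy5 under 1% of Cy3, and the net ratio. The net ratio takes background-subtracted Cy5 over Cy3 without offset or loess, centred per array, for the 836 genes well above background in both channels on every array.

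The procedure was tested on simulated data. With 200 of 3920 genes changed, 87% of those changed by log2 1 and 98% of those changed by log2 2 were recovered, with 12 false calls. In a second simulation, chosen after the data had been seen, the arrays differed only by their measured Cy5 brightness (factors of 0.363 to 3.14), with a spread of 0.3 on the log2 scale. Adding a constant 0.0461% of the Cy3 signal to Cy5 gave 650 genes higher and 616 lower in place of 574 and 599, and 38 lower in place of 0 in the net ratio (97 and 50 at an unadjusted limma p under 0.05). The added share was a low percentile of the Cy5 to Cy3 ratio among the spots brightest in Cy3 on these same arrays. Results were computed with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.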

Results

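Islet RNA of 12-week-old female NOD mice, which develop autoimmune diabetes, was compared with that of NOD.B10 mice, a control strain that shares the NOD background, carries another MHC haplotype and stays free of diabetes. Each of the 12 arrays held the laser-captured, amplified islet RNA of 1 mouse in the Cy5 channel and a common mouse reference RNA in the Cy3 channel, with 6 mice per strain. The comparison asks which transcripts differ in the islets of the diabetes-prone strain. The adenosine A1 receptor gene Adora1 was followed by name, whatever its value. The arrays sat on 4 slides read on 2 days. Slide 1 held NOD replicates 1 and 2 only, and slide 4 held NOD.B10 replicates 2 and 3 only. Slides 2 and 3 each held 2 mice of either strain, so only these give strain differences within a slide.

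The islet channel was brighter on the NOD arrays. Cy5 was well above background on 14 ± 2.55% of spots in NOD (SD, n = 6, range 10.7 to 17.3%) and on 6.21 ± 1.37% in NOD.B10 (range 3.96 to 7.88%; exact 2-sided permutation p = 0.00216, the smallest that all assignments of 6 and 6 arrays can give). The common reference channel was well above background on 50.4 ± 1.94% and 50.1 ± 2.27% of spots (exact permutation p = 0.781). Over 1083 probes that were well above background on all 12 arrays, the unscaled net Cy5 signal was higher in NOD by a median log2 difference of 1.65. The 100 brightest spots held 55.6 ± 5.66% of the net Cy5 signal in NOD and 68.1 ± 4.36% in NOD.B10 (SD, n = 6, exact permutation p = 0.00649). No array had more than 17.3% of its spots well above background in the islet channel, which limits the precision for most genes.

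**Figure D1:**
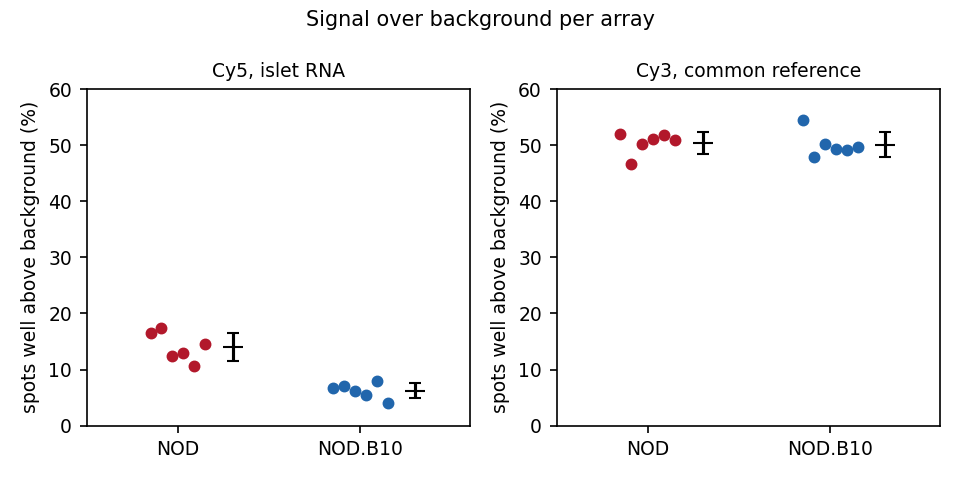
Percent of spots well above background per array in the Cy5 channel (islet RNA, left) and in the Cy3 channel (common reference RNA, right), with 1 point per mouse and the mean and SD of 6 mice beside each strain. The NOD arrays lie between 10.7 and 17.3% in Cy5 and the NOD.B10 arrays between 3.96 and 7.88%, while the strains overlap in Cy3.

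Of 3920 genes tested with limma, 736 were higher and 709 lower in NOD at a Benjamini-Hochberg adjusted p under 0.05, and 458 of these changed at least 2-fold (271 higher, 187 lower). These 2-fold counts take the fitted change, so they include genes given here as a lower bound or without a fold, such as Cd3d and Cat. The largest rises were those of Ctss, a lysosomal protease of antigen-presenting cells (19.6-fold, log2 4.30 ± 0.41, SE, n = 6 per strain), B2m, the light chain of MHC class I (19-fold), Shisa5, an apoptosis-related membrane protein (17.9-fold), and Lyz2, the lysozyme of myeloid cells (16.5-fold). Ptprc, the leukocyte common antigen CD45, was at least 10.3-fold higher, a lower bound because no NOD.B10 array read it well above background. The same holds for Jchain, the joining chain of secreted antibodies (at least 8.85-fold), Ms4a4b, a lymphocyte membrane protein (at least 5.77-fold), and Ms4a1, the B cell antigen CD20 (at least 7.57-fold). Srgn, a proteoglycan of leukocyte granules, rose 11.8-fold and Limd2, a LIM domain protein, 11.5-fold. Apart from 2210010C04Rik, passed over here as an unnamed clone (17.1-fold), the largest falls were those of Amy1, an amylase (22.8-fold, log2 -4.51 ± 1.19, SE, n = 6 per strain), Syn1, a synaptic vesicle protein (11.7-fold), Cpb1, a carboxypeptidase of acinar cells (11.1-fold), and Ins2, 1 of the insulin genes (10.2-fold). Sycn and Pnlip, both of acinar cells, followed (7.89-fold and 7.74-fold), then Prp2, a proline-rich secretory protein (6.98-fold), Chia1, a chitinase (6.88-fold), Sall4, a transcription factor (6.63-fold), and Pip, a secretory protein (6.42-fold). The Cy5 signals of Chia1 and Pip were only 0.052% and 0.039% of Cy3, the size of the 0.0461% Cy3 share added in the simulation. That share was itself taken from low ratios of spots bright in Cy3 on these arrays, so the likeness is no separate evidence. Unscaled net Cy5 was 55.2 in NOD and 60.1 in NOD.B10 for Chia1, and 53.6 and 48.3 for Pip. A fall of these 2 genes and reference signal in the Cy5 channel cannot be told apart. Without NOD.B10 replicate 5 the falls were smaller for Amy1 (log2 -3.46), 2210010C04Rik (-3.22), Cpb1 (-2.51), Sycn (-2.35) and Pnlip (-2.08), and without NOD.B10 replicate 3 for Syn1 (-2.93). Leaving out NOD replicate 5 or NOD.B10 replicate 4 took Syn1 to -4.15 or -4.16, and leaving out NOD replicate 4 or NOD.B10 replicate 3 took 2210010C04Rik to -4.83 or -4.80. With slide as a fixed term Syn1 stood at -1.32 (adjusted p = 0.157), Sall4 at -1.45 (0.151), Prp2 at -1.53, Chia1 at -1.92 and Pip at -2.09.

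Array brightness weighs on these counts. When arrays were simulated that differed in Cy5 brightness alone, the same steps called 574 genes higher and 599 lower with limma. Of these 146 changed at least 2-fold, and 410 of the 599 were also called lower in the data. Simulated and measured changes correlated at r 0.375 across genes. Of the gene lists, fry then called 16 higher and 5 lower. The 16 include the 8 immune lists, higher in the data too. They also include beta cell (1.02), autoantigen (0.60) and glucose sensing (0.59) lists, whose measured means were negative. Simulated means were -0.02 for adenosine signalling, -0.10 for ribosomal proteins and -0.15 for acinar cells. All 736 genes called higher had a higher unscaled net Cy5 signal in NOD, but only 48 of the 709 called lower had a lower one, so lower calls are lower relative to the brightness of the array. Of the 709, 464 were well above background on more NOD than NOD.B10 arrays, and Calr, Cat, Cyc1, Gc and Postn were so on no NOD.B10 array. Ada, Krt18 and Ndufv1 were well above background on only 1 NOD.B10 array each, so their log2 values compare NOD with signals mostly near background. Of 446 tested genes with Cy5 under 1% of Cy3, 401 were called lower and 1 higher. With the share of spots well above background as a covariate, which the strains do not share, 3 genes were higher and 0 lower in limma (153 and 134 at an unadjusted p under 0.05), and fry called 0 lists (6 at an unadjusted p under 0.05). The means of the T cell (-0.09) and proliferation (-0.07) lists turned negative there. Of the 736 and 709 calls Cy5 alone ended 139 and 572, the scanner's processed ratios 164 and 511 and slide as a fixed term 378 and 362. The values of 254 and 281 of these genes moved by over 1.5 times with Cy5 alone, 562 and 260 with the scanner's ratios, 250 and 351 with median centring and 2 and 13 with slide fixed. Slide as a fixed term left 361 genes higher and 354 lower, slide 2 alone 38 and 46, and slide 3 alone 1 and 1. Median centring instead of loess gave 1980 higher and 0 lower (2 lower at an unadjusted p under 0.05) and shifted the median change of all genes to 0.44. That median was -0.0056 in the reported values, 0.43 with the scanner's processed ratios and -0.28 with the net ratio of 836 genes bright on every array. Values of genes and lists under another scaling are given relative to that shift, and their tests are of the unshifted values. The net ratio, a measure that gave 0 calls in the brightness simulation (limma, 50 at an unadjusted p under 0.05) and 38 lower calls when a constant share of Cy3 was added to Cy5, had 136 genes higher and 264 lower.

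Genes of leukocytes were higher in NOD islets in all 4 lists of leukocyte markers that could be tested. The filter admits genes bright in NOD alone, so the numbers tested depend on the NOD signal. Members well above background in 1 strain only, and higher in that strain, were 7 of 8 (T cell), 9 of 9 (B and plasma cell), 4 of 11 (macrophage and dendritic cell) and 4 of 4 (cytotoxic and NK cell). Of all 736 genes called higher, 350 were well above background on no NOD.B10 array. Of those called lower, 0 were well above background on no NOD array. In the T cell list 6 of 8 genes rose (8 adjusted over the list alone). Among them were Il7r, the interleukin-7 receptor (at least 3.69-fold), Cd3d, a chain of the T cell receptor complex, and the T cell surface protein Cd5, the last 2 with no lower bound above 1. In the B and plasma cell list 8 of 9 rose (9 adjusted over the list alone). These include Jchain, Ms4a1, Pou2af1, a B cell transcriptional coactivator (at least 5.01-fold), and Bank1, a B cell scaffold protein (at least 1.05-fold, but log2 -0.011 with median centring). In the macrophage and dendritic cell list 9 of 11 rose (9 adjusted over the list alone), Ctss and Lyz2 among them. Others were Mpeg1, a pore-forming protein of macrophages (4.47-fold), and C1qc, a complement chain, for which no fold is given, as only 1 of 6 NOD.B10 arrays read it well above background. The cytotoxic and NK cell list rose in 4 of 4 genes (4 adjusted over the list alone). These were Ccl5, a T cell and NK cell chemokine (at least 2.38-fold), Nkg7, a granule protein (at least 2.47-fold), Klrd1, the NK receptor CD94 (at least 1.52-fold), and Il2rb, an interleukin-2 receptor chain, with no lower bound above 1 and log2 -0.15 with median centring.

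The list means were 1.09 (T cell), 1.85 (B and plasma cell), 1.54 (macrophage and dendritic cell) and 1.71 (cytotoxic and NK cell) on the log2 scale, with fry adjusted p of 0.00232, 0.000321, 2.16e-05 and 0.000467. Brightness alone, as simulated, also raised these 4 lists in fry, with means of 0.46, 0.42, 0.14 and 0.48 and with 6 of 8, 6 of 9, 2 of 11 and 3 of 4 genes called higher. In camera with an estimated correlation the 4 lists did not pass (adjusted p = 0.302, 0.273, 0.167 and 0.273). With the preset correlation they passed camera (adjusted p = 0.000995, 1.2e-05, 1.2e-05 and 0.00293). Their means with slide as a fixed term were 0.85, 1.62, 1.33 and 1.34. Within slide 2 they were 0.95, 1.77, 1.40 and 1.29, and within slide 3 0.75, 1.46, 1.25 and 1.38. With members at background in NOD.B10 put at their lower bound (0 where it is not above 1), the list medians went from 0.85 to 0 for T cells, from 1.32 to 0.96 for B and plasma cells, from 1.94 to 0.93 for cytotoxic and NK cells and from 1.08 to 0.76 for macrophages and dendritic cells. Cd5 (adjusted p = 0.0813) and Il2rb (0.119) did not pass limma with slide as a fixed term. The probe of Cd3e, a T cell receptor chain, read log2 -0.13 and that of Cd79a, a B cell receptor chain, 0.01, and neither was well above background on any array. Ptprc has 2 further probes, at log2 0.06 and -0.02, which were not well above background on any array either.

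**Figure D2:**
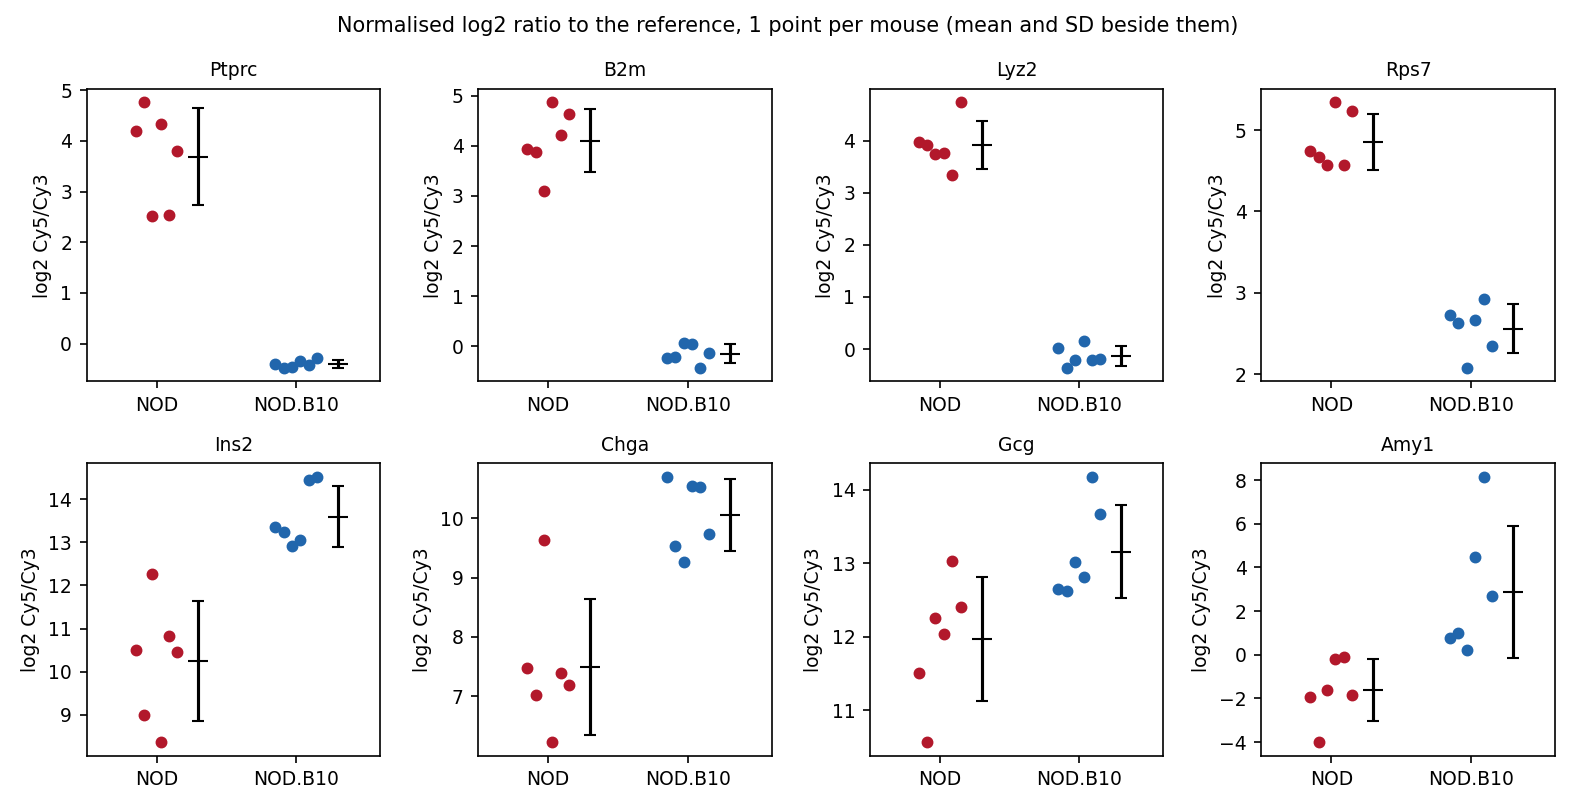
Normalised log2 Cy5/Cy3 ratio of 8 named genes, 1 panel per gene and 1 point per mouse, with the mean and SD of 6 mice beside each strain. Every NOD mouse lies above every NOD.B10 mouse for Ptprc, B2m, Lyz2 and Rps7, and below for Ins2 and Amy1 (normalised to the array, where array brightness takes part), while Chga and Gcg overlap and Gcg turns to log2 0.97 with Cy5 alone and 0.77 with median centring.

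Chemokine, interferon-induced and antigen presentation genes rose with the leukocyte lists. Members well above background in 1 strain only, and higher in that strain, were 10 of 13 (chemokines), 12 of 16 (interferon-induced), 4 of 13 (MHC class I) and 4 of 4 (MHC class II). Among 13 chemokine and lymphoid organisation genes 11 rose (11 adjusted over the list alone). They include Ccl19, which draws lymphocytes into lymphoid tissue (at least 5.46-fold), Cxcl10 and Cxcl9, interferon-induced chemokines (at least 3.02-fold and 1.68-fold), and Ccl8, a monocyte chemokine (at least 2.29-fold). The chemokines Cxcl12 (log2 -0.85) and Cx3cl1 (on no NOD.B10 array well above background), named after their values were seen, were lower. Of 16 interferon-induced genes 13 rose (14 adjusted over the list alone). They include the interferon-inducible GTPases Igtp (at least 3.86-fold), Gbp2 (at least 2.81-fold), Gbp3 (at least 2.57-fold) and Ifi47 (at least 2.67-fold). Of 13 MHC class I presentation genes 9 rose (11 adjusted over the list alone). Among these were B2m, the class I chains H2-K1 (5.57-fold) and H2-M3 (4.45-fold) and the proteasome activator Psme2 (2.31-fold). H2-Q10, a class I chain named after its value was seen, was lower (log2 -0.97). All 4 MHC class II presentation genes rose (4 adjusted over the list alone), namely the invariant chain Cd74 (at least 4.64-fold), the class II chain H2-Ab1 (at least 2.15-fold), H2-DMb1 (at least 1.33-fold) and H2-Oa, with no lower bound above 1.

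The list means were 1.56 (chemokines), 1.00 (interferon-induced), 1.05 (MHC class I) and 1.72 (MHC class II), with fry adjusted p of 3.31e-05, 2.16e-05, 2.16e-05 and 0.00114. Simulated brightness raised these 4 lists in fry too, with means of 0.50, 0.26, 0.20 and 0.63 and with 11 of 13, 7 of 16, 2 of 13 and 3 of 4 genes called higher. With an estimated correlation none passed camera (adjusted p = 0.167, 0.167, 0.167 and 0.302). With the preset correlation all 4 passed camera (adjusted p = 4.68e-05, 3.15e-07, 4.84e-05 and 0.00403). With slide as a fixed term the means were 1.31, 0.87, 1.00 and 1.42, within slide 2 1.14, 0.75, 0.85 and 1.63, and within slide 3 1.48, 0.99, 1.14 and 1.20. With members at their lower bound the list medians went from 1.54 to 0.75 for chemokines, from 0.78 to 0.39 for interferon-induced genes, from 0.71 to 0.56 for MHC class I and from 1.63 to 0.76 for MHC class II. H2-DMb1 did not pass limma with slide as a fixed term (adjusted p = 0.128). With the scanner's ratios B2m stood at log2 2.56 and H2-K1 at 0.63, and with Cy5 alone B2m at 3.16, H2-K1 at 1.22, H2-M3 at 0.74 and Psme2 at 0.57. The strains carry different MHC haplotypes, so probes for H2-K1, H2-M3, H2-Q10, H2-Ab1, H2-Oa and H2-DMb1 can bind the strains' transcripts unequally, which does not concern B2m or Cd74. H2-K1 has 2 further probes (log2 -0.07 and -0.11) and so has H2-Ab1 (0.02 and -0.08), none well above background on any array. Over the 77 genes of these 8 lists, of which 63 were higher and 3 lower, the mean log2 ratio was higher in NOD by 1.34 (exact permutation p = 0.00216, n = 6 per strain), by 1.12 within slide 2 and by 1.18 within slide 3.

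Other genes in the MHC region also rose, 4 of 15 tested (4 adjusted over the list alone): Rps18, a ribosomal protein (4.83-fold), Ubd, the ubiquitin-like protein FAT10 (at least 1.20-fold), Aif1, a macrophage protein (at least 1.55-fold), and Clic1, a chloride channel (log2 0.68). Their mean was 0.50 (fry adjusted p = 4.59e-05; adjusted p = 0.167 with an estimated correlation), 0.43 with slide as a fixed term, 0.33 within slide 2 and 0.52 within slide 3. Of 35 ribosomal protein genes 29 rose (30 adjusted over the list alone). Examples are Rps7 (4.89-fold, log2 2.29 ± 0.18, SE, n = 6 per strain), Rps27 (4.78-fold), Rps3 (4.27-fold) and Rpl22 (4.22-fold). Their mean was 1.36 (fry adjusted p = 4.53e-05; adjusted p = 0.167 with an estimated correlation), 1.37 with slide as a fixed term, 1.55 within slide 2 and 1.18 within slide 3. In the net ratio 22 of 22 members bright on every array rose. With the scanner's processed ratios Rps7 stood at log2 0.33, Rps3 at 0.40, Rps18 at 0.43, Rpl22 at 1.30 and Rps27 at 0.31, which did not pass (adjusted p = 0.0654), and Clic1 turned to -0.04. With slide as a fixed term Clic1 was 0.30 and did not pass (adjusted p = 0.285), nor did it without slide 4 (0.0921) or with Cy5 alone (0.345), and Ubd did not pass with median centring (0.0735).

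Some apoptosis and proliferation genes rose, and few immediate early genes changed. Of 13 apoptosis genes 8 rose (9 adjusted over the list alone). Examples are Casp4, an inflammatory caspase (no fold is given, as only 1 of 6 NOD.B10 arrays read it well above background), Tnfaip3, an inhibitor of NF-kappaB signalling (at least 1.17-fold), Bcl2, which blocks apoptosis (at least 1.15-fold), and Bcl2l11, which promotes it (at least 1.5-fold). Of 12 proliferation genes 7 rose (7 adjusted over the list alone). Examples are the replication factors Mcm6 (at least 3.76-fold), Mcm4 (at least 1.51-fold) and Mcm7 and the cell cycle regulator Cdc20 (at least 1.44-fold). Of 8 immediate early and stress genes, which handling of tissue can induce, Junb, a transcription factor, rose 5.12-fold (log2 2.36 ± 0.13, SE, n = 6 per strain), Btg2, an antiproliferative gene, rose (log2 0.69) and Hsph1, a heat shock protein, fell (log2 -1.03). Adjusted over the list alone, 2 were higher and 1 lower. The list means were 0.65, 0.53 and 0.27 (fry adjusted p = 0.00157, 0.00376 and 6.08e-05; adjusted p = 0.302, 0.339 and 0.471 with an estimated correlation), and the immediate early median was 0.077. Simulated brightness gave 0.17, -0.034 and 0.14, and raised the apoptosis list in fry. The measured means were, with slide as a fixed term, 0.56, 0.37 and 0.30, within slide 2 0.49, 0.38 and 0.36, and within slide 3 0.63, 0.36 and 0.24. Mcm7 (adjusted p = 0.146) and Btg2 (0.261) did not pass limma with slide as a fixed term, nor without slide 4 (0.0508 and 0.122). Cy5 alone also ended the call of Btg2 (0.268), and median centring those of Tnfaip3 (0.0630) and Hsph1 (0.934). Btg2 lost its call without NOD replicate 2 (adjusted p = 0.0612), 4 (0.0576) or 6 (0.0513) and without NOD.B10 replicate 2 (0.0551), 3 (0.0633) or 5 (0.0507).

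Several genes of islet endocrine function were lower in NOD relative to the array, while others were not called. Ins2 fell 10.2-fold (log2 -3.35 ± 0.56, SE, n = 6 per strain, limma adjusted p = 0.000639) and its second probe read log2 -3.51. Slc2a2, the glucose transporter of beta cells, fell 5.98-fold, Chga, a secretory granule protein, 5.91-fold, Pcsk2, a prohormone convertase, 2.66-fold, and Ins1, the other insulin gene, 3.37-fold. Iapp, the beta cell hormone amylin, stood at log2 -1.53 (limma adjusted p = 0.0564), Sst, somatostatin, at -0.44 (0.376) and Ppy, pancreatic polypeptide, at -0.12 (0.546). Iapp was -0.72 with slide as a fixed term (adjusted p = 0.411) and -0.76 without slide 4 (0.266), but passed with Cy5 alone (-2.03, 0.000353) and with the scanner's ratios (-2.78, 0.000546). Sst passed as lower with the scanner's ratios (-1.72, adjusted p = 0.00503) and in the net ratio (-0.69, 0.00554) and as higher with median centring (0.52, 0.00320). Gcg, glucagon, fell 2.28-fold after loess and was also lower in the net ratio (log2 -0.48, adjusted p = 0.0301) and with the scanner's ratios (-2.06, 0.00338), but turned to log2 0.97 with Cy5 alone and to 0.77 with median centring. Without scaling, the net Cy5 signal of Ins2 was 12510 in NOD and 14228 in NOD.B10, that of Ins1 1662 and 1606, that of Chga 3495 and 3402, and that of Gcg 28080 and 12412. Within each array the insulin genes stood at log2 -2.97 ± 1.12 relative to Gcg in NOD and at -1.35 ± 0.27 in NOD.B10 (SD, n = 6), a difference of -1.63 or 3.09-fold lower in NOD (exact permutation p = 0.0152). That difference was -1.60 within slide 2 and -1.88 within slide 3, and NOD replicate 3, at -1.06, lay above all 6 NOD.B10 mice, so the value within slide 2 rests on NOD replicate 4 (-4.49).

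The islet autoantigen list was lower in 6 of 10 genes (7 adjusted over the list alone), of which Ins1, Ins2 and Chga also belong to other endocrine lists. Another was Tspan7, a membrane protein that is a target of islet autoantibodies, at log2 -0.83. Its mean was -1.16 (fry adjusted p = 0.00567; adjusted p = 0.334 with an estimated correlation), -1.14 with slide as a fixed term (adjusted p = 0.0574), -1.07 within slide 2 and -1.20 within slide 3. The glucose sensing and excitability list was lower in 2 of 3 genes (2 adjusted over the list alone), Slc2a2 and Pcx, an anaplerotic enzyme (2.74-fold). Its mean was -1.33 (fry adjusted p = 0.0166; adjusted p = 0.423 with an estimated correlation), -1.22 with slide as a fixed term (adjusted p = 0.0784), -0.83 within slide 2 and -1.62 within slide 3. It did not pass without NOD replicate 5 (adjusted p = 0.0632). The alpha cell list was lower in 2 of 4 genes (2 adjusted over the list alone), Gcg and Gc, a vitamin D binding protein that no NOD.B10 array read well above background, so that no fold is given. Its mean was -0.72 but turned to 0.15 with Cy5 alone and to 0.13 with median centring. It passed fry (adjusted p = 0.0259; adjusted p = 0.441 with an estimated correlation), with -0.63 with slide as a fixed term, -0.35 within slide 2 and -0.90 within slide 3. Median centring ended the calls of Tspan7 (adjusted p = 0.623), Pcx (0.695) and Gc (0.80), and Cy5 alone that of Gc (0.938). The alpha cell list did not pass without NOD replicate 3 (adjusted p = 0.327), 4 (0.318), 5 (0.247) or 6 (0.258).

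The beta cell list mean was -1.22 with 3 of 10 genes lower, Ins2, Slc2a2 and Ins1 (3 adjusted over the list alone), and the endocrine granule list mean was -0.71 with 6 of 13 lower (7 adjusted over the list alone). Neither passed fry (adjusted p = 0.0504 and 0.0718) or camera with an estimated correlation (adjusted p = 0.442 and 0.447). Both passed camera with the preset correlation (adjusted p = 0.0187 and 0.0159). In the exact permutation of mouse means the beta cell list passed (adjusted p = 0.0278) and the granule list did not (0.0502). Without NOD replicate 3 both passed fry, at -1.72 (adjusted p = 0.000217) and -1.02 (0.00019). With slide as a fixed term the means were -1.23 and -0.74, within slide 2 -1.03 and -0.56, and within slide 3 -1.42 and -0.92. In the net ratio of bright genes 5 of 5 beta cell genes and 9 of 9 granule genes were lower (means -1.42 and -1.37, fry adjusted p = 0.00112 and 0.000343), among them Ins2 (-1.72), Iapp (-2.0), Chga (-1.76) and Pcsk2 (-1.17). Neither list passed camera there (adjusted p = 0.329 for both with an estimated correlation). Median centring ended the calls of Ins2 (log2 -0.50, adjusted p = 0.868), Chga (-0.51, 0.862) and Slc2a2 (-1.08, 0.0557) and turned Pcsk2 to 0.05. As it called 0 genes lower, it also ended the calls of Ins1 and Pcsk1n. Cy5 alone ended those of Ins2 (-0.68, 0.211), Chga (-1.01, 0.14) and Pcsk2 (-1.28, 0.0759), but Slc2a2 (-1.70, 0.000716) and Pcsk1n, a granule peptide gene (-1.62, 0.00868), passed there. Ins1 (-1.94, adjusted p = 0.121) and Pcsk1n (-1.43, 0.102) did not pass limma with slide as a fixed term. Leaving out 1 mouse, Ins1 kept its call only without NOD replicate 3 or NOD.B10 replicate 3 and otherwise stood between log2 -1.34 and -1.82 (adjusted p 0.0552 to 0.0812). Pcsk1n kept its call only without NOD replicate 1 or 3 or NOD.B10 replicate 2 (otherwise limma adjusted p 0.0580 to 0.0888). Gcg lost its call without NOD replicate 1 (adjusted p = 0.0582) or NOD.B10 replicate 5 (0.0578) or 6 (0.0568). Iapp passed without NOD replicate 3 (0.0220) or NOD.B10 replicate 1 (0.0378) or 6 (0.0326).

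**Figure D3:**
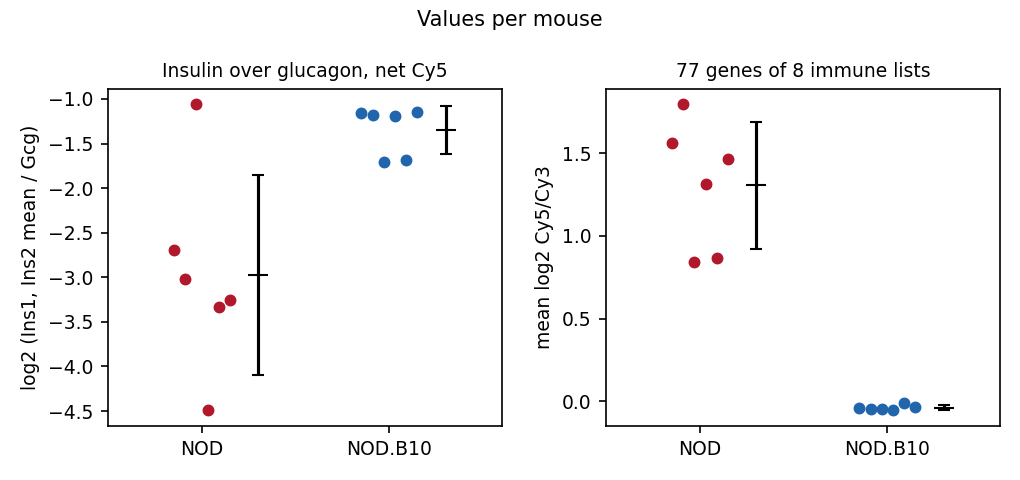
Values per mouse with the mean and SD of 6 mice beside each strain: log2 net Cy5 signal of the insulin genes over that of Gcg within each array (left) and mean log2 Cy5/Cy3 ratio over 77 genes of 8 immune lists (right). The immune means lie between 0.84 and 1.79 in NOD and between -0.05 and -0.01 in NOD.B10, while NOD replicate 3 lies at -1.06 on the left, above the other NOD mice.

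Genes of exocrine cells, which a captured islet section can include at its rim, were lower in NOD and varied widely between mice. In the acinar cell list 9 of 13 genes fell (13 adjusted over the list alone). Examples are Amy1, 2210010C04Rik, a trypsinogen (17.1-fold), Cel, a bile salt lipase (3.05-fold), and Zg16, a zymogen granule protein (2.45-fold). The list mean was -2.65 (fry adjusted p = 0.0332; adjusted p = 0.434 with an estimated correlation), -2.95 with slide as a fixed term (adjusted p = 0.0545), -1.89 within slide 2 and -4.01 within slide 3. The NOD.B10 mice had a SD of 2.09 in this list mean. It did not pass without NOD replicate 1 (adjusted p = 0.0568), 2 (0.0704), 3 (0.0567) or 6 (0.0621) or NOD.B10 replicate 4 (0.0663) or 6 (0.0504), nor with Cy5 alone (-1.40, 0.0743), and without NOD.B10 replicate 5 it was -1.95. Without the same mouse, 2210010C04Rik lost its call for NOD replicates 1 (0.0535) and 2 (0.0576) and NOD.B10 replicate 4 (0.0564). Cpb1 lost it for NOD replicates 1 (0.0517), 2 (0.0663) and 6 (0.0544) and NOD.B10 replicate 4 (0.0620). Sycn lost its call for NOD replicates 1 (0.0630), 2 (0.0664) and 3 (0.0522) and NOD.B10 replicates 4 (0.0609), 5 (0.0583, at log2 -2.35) and 6 (0.0582). Pnlip lost it for NOD replicates 1 (0.0661), 2 (0.0808), 3 (0.0556) and 6 (0.0691) and NOD.B10 replicates 4 (0.0804), 5 (0.0508, at log2 -2.08) and 6 (0.0565). Pnlip (log2 -3.57, adjusted p = 0.0512) and Zg16 (-1.36, 0.0683) did not pass with slide as a fixed term. Sall4 turned to log2 0.51 with Cy5 alone and to 0.15 with median centring. Median centring ended the calls of Amy1 (-1.21, adjusted p = 0.317), 2210010C04Rik (-0.89, 0.604), Cpb1 (-1.13, 0.361), Sycn (-0.54, 0.883), Pnlip (-1.05, 0.334), Cel (-0.55, 0.723) and Zg16 (-0.45, 0.982). It also ended those of Syn1 (-0.065, 0.297), Prp2 (-0.86, 0.253), Chia1 (-0.39, 0.794) and Pip (-0.26, 0.235). Cy5 alone ended those of 2210010C04Rik (-2.04, 0.0632), Cpb1 (-1.84, 0.0553), Pnlip (-1.56, 0.109), Cel (-0.70, 0.0875) and Zg16 (-0.48, 0.301), while Amy1 (-2.26, 0.0228) passed.

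In the Reg family, secreted proteins of regenerating and inflamed pancreas, Reg3b was lower among 3 genes (log2 -1.43; 2 genes adjusted over the list alone). The mean was -1.62 (fry adjusted p = 0.0285; adjusted p = 0.431 with an estimated correlation), -1.91 with slide as a fixed term, -0.73 within slide 2 and -3.08 within slide 3. It did not pass the exact permutation of mouse means (adjusted p = 0.0758), with Cy5 alone (-0.87, 0.325) or with the scanner's ratios (-1.57, 0.259), nor without NOD replicate 6 (0.0567) or NOD.B10 replicate 4 (0.0534). The duct cell list was lower in 2 of 3 genes (2 adjusted over the list alone), the keratins Krt8 (log2 -0.64) and Krt18 (-0.48). The mean was -0.30 but turned to 0.15 with median centring. It passed fry (adjusted p = 0.0259; adjusted p = 0.434 with an estimated correlation) but not with slide as a fixed term (-0.19, adjusted p = 0.215), the exact permutation of mouse means (adjusted p = 0.172) or without NOD replicate 2 (0.0508). Krt18 did not pass with slide as a fixed term either (adjusted p = 0.0882), and Cy5 alone ended the calls of Krt8 (0.397), Krt18 (0.742) and Reg3b (0.782). Within slide 2 the duct mean was -0.01 and within slide 3 -0.37.

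Oxidative phosphorylation, antioxidant and adenosine signalling lists were lower relative to the array. Of 28 oxidative phosphorylation genes 15 fell (16 adjusted over the list alone). Examples are Cyc1, cytochrome c1 (no fold is given, as no NOD.B10 array read it well above background), and the complex I subunits Ndufv1 (-0.66, with only 1 NOD.B10 array well above background), Ndufb3 (-0.66) and Ndufa9 (-0.53), where median centring turned Ndufb3 to 0.26 and Ndufa9 to 0.19 and slide as a fixed term ended the call of Ndufa9 (-0.34, adjusted p = 0.103). The list mean was -0.40 (fry adjusted p = 0.000385; adjusted p = 0.193 with an estimated correlation), -0.35 with slide as a fixed term and within slide 2 and -0.34 within slide 3. It was 0.56 with median centring, -0.07 with Cy5 alone (adjusted p = 0.247) and 0.20 in the net ratio (0.404). Of 13 antioxidant genes 8 fell and 1 rose (10 and 1 adjusted over the list alone). Examples are Cat, catalase (no fold is given, as no NOD.B10 array read it well above background), Mt1, a metallothionein (2.20-fold lower), Sod2, a superoxide dismutase (1.57-fold lower, log2 0.05 with median centring and 0.011 in the net ratio), and Txn1, thioredoxin (log2 0.58). The antioxidant mean was -0.54 (fry adjusted p = 0.000849; adjusted p = 0.273 with an estimated correlation), -0.49 with slide as a fixed term, -0.45 within slide 2 and -0.53 within slide 3. It was 0.11 with median centring and -0.088 in the net ratio (adjusted p = 0.129). Brightness alone, as simulated, gave -0.38 for oxidative phosphorylation and -0.44 for antioxidant genes. In the adenosine signalling list 2 of 4 genes were lower (2 adjusted over the list alone), the enzymes adenosine kinase, Adk (log2 -1.22, but 0.33 with median centring), and adenosine deaminase, Ada (-0.67, but 0.46 with the scanner's ratios). The adenosine mean was -0.44 (fry adjusted p = 0.000467; adjusted p = 0.302 with an estimated correlation), -0.36 with slide as a fixed term, -0.40 within slide 2 and -0.33 within slide 3. It was 0.08 with median centring, -0.04 with the scanner's ratios (adjusted p = 0.493) and -0.21 with Cy5 alone (0.172). Of the 10 genes named here, Cy5 alone ended the calls of all but Mt1 and Txn1, and median centring that of Mt1 (log2 -0.12, adjusted p = 0.171).

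The remaining lists did not pass fry. The delta and PP cell list, with Rbp4, a retinol carrier, lower (3.28-fold, but log2 0.34 with median centring), and Hhex, a transcription factor of delta cells, higher (log2 0.52), was mixed. Its mean of -0.31 turned to 0.25 with median centring (fry adjusted p = 0.119; adjusted p = 0.619 with an estimated correlation). It passed without NOD.B10 replicate 2 (-0.44, adjusted p = 0.0298), and Hhex kept its call only without NOD replicate 3 or 5 or NOD.B10 replicate 1 (otherwise adjusted p 0.0584 to 0.0949) and did not pass with slide as a fixed term (0.273). The unfolded protein response list was lower in 3 of 14 genes, the chaperone gene Dnajb9 (log2 -0.72), Chac1 (-0.67) and Calr, calreticulin, which no NOD.B10 array read well above background. The mean was -0.36 (adjusted p = 0.0887; adjusted p = 0.476 with an estimated correlation) and passed without NOD replicate 3 (-0.54, 0.00019). None of the 3 passed limma with slide as a fixed term (adjusted p = 0.0951, 0.0733 and 0.0935). Calr lost its call without NOD replicate 4 (adjusted p = 0.0599) or NOD.B10 replicate 4 (0.0667), 5 (0.0600) or 6 (0.0742). Of 6 endothelial genes 0 were called in limma (0 at an unadjusted p under 0.05), with Flt1, a VEGF receptor, at log2 -0.17 and Ptprb, a phosphatase of endothelial cells, at -0.30. The mean of -0.34 (adjusted p = 0.0891) passed without NOD replicate 1 (-0.45, 0.0478), and Ptprb passed without NOD replicate 5 (0.0371). In the fibroblast and matrix list the cytoskeletal gene Vim (3.30-fold) and the proteoglycan gene Dcn (2.40-fold) were higher, of 11 genes, but Dcn did not pass with slide as a fixed term (log2 1.12, adjusted p = 0.0739) or with the scanner's ratios (0.39, 0.113). The collagen gene Col1a1 (log2 -0.85, but 0.58 with median centring and 0.32 in the net ratio) and Postn (on no NOD.B10 array well above background, and higher with the scanner's ratios) were called lower. Postn lost its call without NOD replicate 5 (adjusted p = 0.0665) or NOD.B10 replicate 1 (0.0932), 2 (0.0607), 4 (0.0870), 5 (0.0696) or 6 (0.102). Its mean was 0.20 and its median -0.03 (adjusted p = 0.679), and it passed without NOD replicate 3 (0.29, 0.0293). The glycolysis mean was -0.14, turning positive in several settings (0.69 with median centring; adjusted p = 0.505), with Ldha, lactate dehydrogenase, higher (log2 0.91) and 2 of 8 genes lower, Pgam1 and Slc16a1, neither of which passed with slide as a fixed term (adjusted p = 0.120 and 0.409), and the list passed without NOD replicate 5 (-0.28, 0.0234). Slc16a1 lost its call without NOD replicate 1, 2, 3 or 6 or NOD.B10 replicate 1, 2, 3, 4 or 6 (limma adjusted p 0.0520 to 0.0941). With the scanner's ratios it turned to log2 1.35 (limma adjusted p = 0.000525). Of 3 endocrine transcription factors, Neurod1 (log2 0.09) and Foxa2 (0.11) among them, limma called 0 (0 at an unadjusted p under 0.05). Their mean was 0.04 (adjusted p = 0.765) but turned to -1.32 with the scanner's ratios and to -0.016 without NOD.B10 replicate 6. Neurod1 turned to -0.060 without NOD replicate 3 and to -0.0025 without NOD.B10 replicate 6. With slide as a fixed term the delta and PP cell mean was -0.42 and passed (adjusted p = 0.0262), and the means were -0.28 (unfolded protein response), 0.19 (fibroblast) and 0.05 (glycolysis). Within slides 2 and 3 they were -0.55 and -0.29 (delta and PP cell), -0.09 and -0.46 (unfolded protein response), 0.02 and -0.02 (endothelial), 0.16 and 0.22 (fibroblast), -0.19 and 0.29 (glycolysis) and 0.09 and -0.12 (transcription factors). The Schwann cell, adipocyte, neutrophil and inflammatory cytokine lists had 1 tested member each and were not tested. Their members were Mbp, a myelin protein (log2 0.66), Fabp4, a fatty acid carrier (-1.03, but 0.058 with median centring and in the net ratio), S100a9, a neutrophil protein (-2.04, and -0.98 in arrays simulated with brightness alone), and Il1b, interleukin-1 beta, with no lower bound above 1, all past limma's threshold. Median centring, which called 0 genes lower, ended the call of S100a9. Mbp (adjusted p = 0.160), Fabp4 (0.247) and Il1b (0.162) did not pass with slide as a fixed term. Fabp4 kept its call only without NOD replicate 4 or 5 or NOD.B10 replicate 5 (otherwise adjusted p 0.0549 to 0.0812), and Il1b lost its call without any of the NOD.B10 mice (adjusted p 0.0538 to 0.0759).

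**Figure D4:**
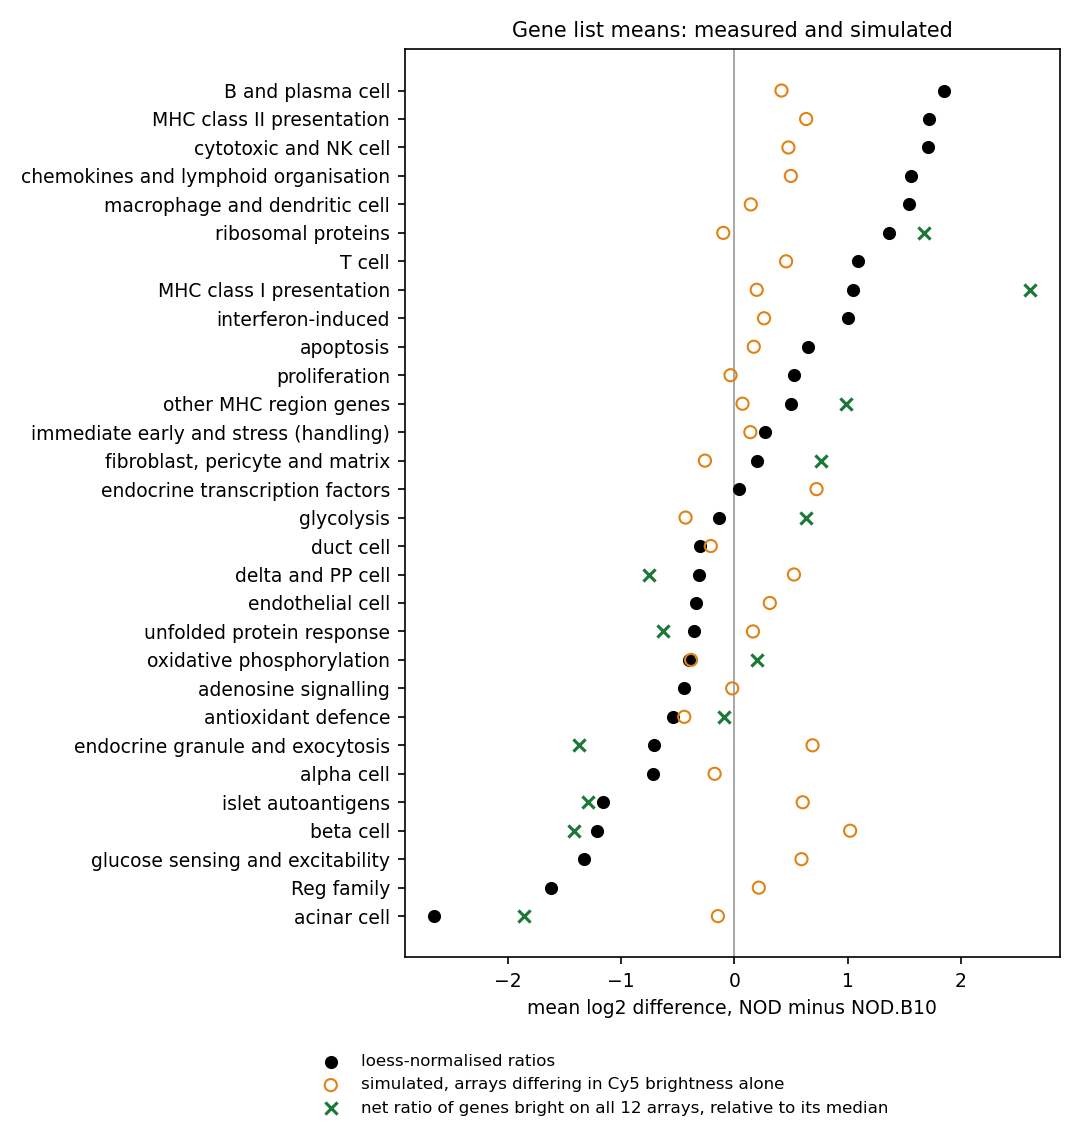
Mean log2 difference, NOD minus NOD.B10, of each of the 30 tested gene lists from loess-normalised ratios (filled points), from simulated arrays that differ in Cy5 brightness alone (open points) and, for lists with at least 3 genes bright on all 12 arrays, from their net ratio relative to its median change (crosses). The simulated means of oxidative phosphorylation (-0.38) and antioxidant genes (-0.44) lie near the measured ones (-0.40 and -0.54), while those of the beta cell (1.02) and granule (0.69) lists lie on the other side of 0 from the measured ones.

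Adora1, the adenosine A1 receptor, was too dim for the filter. Its brightest probe read log2 -0.41 ± 0.32 (SE, n = 6 per strain, limma adjusted p = 0.661 over all probes) and was well above background on 0 of 6 NOD and 3 of 6 NOD.B10 arrays. Of its other 2 probes, 1 read 0.02 (adjusted p = 0.970) and 1 -0.23 (adjusted p = 0.0319), and neither was well above background on any array. The value of the brightest probe rested on slide 4, whose NOD.B10 replicates 2 and 3 had net Cy5 signals of 64 and 43 and net reference signals of 509 and 409, against at most 28.5 for the reference on the other arrays. Without slide 4 it was 0.13 and with slide as a fixed term 0.04, and without NOD.B10 replicate 2 or 3 -0.15 or -0.24. A strain difference in Adora1 was not detectable at this signal.

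In the reference channel, meant to carry the same RNA on all 12 arrays, limma called 0 of 3920 genes between the strains (194 at an unadjusted p under 0.05), and 1 without NOD.B10 replicate 1. Slide 4 against the rest gave 2630 called genes in that channel, and the reference signals of slide 4 correlated with those of other arrays at r 0.944 to 0.972 across genes, against at least 0.986 between arrays of slides 1 to 3. Why the reference signals of slide 4 differed was not tested. In the normalised ratios, replicates correlated across genes at r 0.709 to 0.930 in NOD and 0.715 to 0.953 in NOD.B10, and mice of different strains at 0.464 to 0.802, where genes are not independent replicates. A total of 372 genes called higher and 289 called lower had no overlap between NOD and NOD.B10 mice. These were counted among called genes, which the test picks for such separation, and Cy5 brightness separates the strains too, so the counts add no support.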

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

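Of the tests in this part, those of the lower calls with Cy5 under 1% of Cy3, of oxidative phosphorylation, of the immune lists with a 10th percentile floor, with Cy5 alone, by slide and against endothelial genes, and of the insulin genes against brightness and dilution were chosen after the result was seen.

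In 17 of 294 groups of 6 values, 1 mouse lay farther from its nearest neighbour, relative to the range of its group, than the 95% critical value of Dixon's test, where chance gives this in about 1 in 20 groups. NOD replicate 3 was that mouse in 9 of them. Its list means were apart for endocrine granule genes (log2 ratio 3.67, nearest 2.50), glucose sensing (1.78, nearest -0.07), the unfolded protein response (1.1, nearest 0.13) and, on the low side, MHC class I presentation (0.79, nearest 1.20). Its genes were apart for Chga (9.63, nearest 7.47), Sst (9.27, nearest 8.02), Slc2a2 (1.68, nearest -0.73), Foxa2 (1.07, nearest 0.33) and Calr (-0.039, nearest -0.28). Among the NOD.B10 mice, replicate 5 stood apart for Cel (2.21, nearest 0.38) and Cxcl10 (-0.33, nearest -0.07), and replicate 6 for the proliferation list (-0.091, nearest -0.19). Replicate 3 stood apart for Clic1 (-0.15, nearest 0.36), replicate 1 for Mpeg1 (0.26, nearest 0.05) and replicate 4 for Sall4 (7.70, nearest 9.93). In the reference channel the share of spots well above background was 46.7% for NOD replicate 2 (nearest 50.2%) and 54.4% for NOD.B10 replicate 1 (nearest 50.2%).

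The share of splits with as many calls was under 0.05 for all 5 counts between NOD and NOD.B10, without adjustment over the 5. This argues against chance for the counts of genes. Of 100 of the 462 splits of the arrays into 6 and 6, the real one included, 1 gave as many genes called higher (736, the highest other 238), 1 as many called lower (709, the highest other 238) and 1 as many changed at least 2-fold (458, the highest other 164). As many lists called higher came from 2 (13, the highest other 13), and as many called lower from 4 (9, the highest other 13). Another split gave the same 13 lists higher and 9 lower, so for the list counts a sample of 100 splits cannot exclude chance. Splits that follow slides called 0 genes with limma and 0 lists with fry, with 376 genes and 3 lists at an unadjusted p under 0.05 for slides 1 and 2 against 3 and 4, and 217 and 3 for slides 1 and 3 against 2 and 4. The splits say nothing on Cy5 brightness, which follows the strains.

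Most genes called lower in NOD had no lower unscaled signal there: 4.49% of the 401 with Cy5 under 1% of Cy3 did, and 9.74% of the 308 others. Of the 446 tested genes of the first kind, 89.9% were called lower, and arrays simulated with brightness differences alone gave 599 lower calls. The oxidative phosphorylation mean, -0.40 after loess, was -0.074 in the net ratio of bright genes as tested (fry adjusted p = 0.404) and 0.20 relative to the median change of those genes. Cy5 brightness with the loess trend may therefore account for most lower calls among dim genes and for the oxidative phosphorylation and antioxidant lists. A real fall smaller than the median brightness difference of 1.65 would also leave the unscaled signal higher, so a strain difference in these transcripts stays open, as untested.

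The 8 immune lists were higher in NOD, as they also were, with means of 0.14 to 0.63, in arrays simulated with brightness alone. The values argue against slide, with a rise of at least 1.12 within slides 2 and 3 and no overlap. For a smaller share of islet RNA, the immune mean was set against the endothelial mean and rose over it by 1.68 (exact permutation p = 0.00216). That test cannot decide, since endothelial cells within islets would fall with that share too. The endothelial difference was -0.34, and -0.0026 with slide as a fixed term. For array brightness 4 forms of a test were tried, and the immune members well above background on all 12 arrays, 5 in number, argue against it, since 100% rose by more than the median bright probe. With signals floored at the lowest well above background the excess over bright probes was 2.09 (their interquartile range 1.37), but that floor was 0 or below on 8 of 12 arrays, where log2 does not exist and 1 was put in, so this form was unsuitable. A floor at the 10th percentile, chosen with those values in view, gave an excess of 0.61 with 67.5% of members above the bright median where 75% was required, and Cy5 alone raised 8 of 8 lists, of which the brightness simulation also raised 1. The means of these lists with Cy5 alone (0.30 to 0.90) all exceed the highest simulated one (0.11), which goes against brightness, but a bound from simulated values was not taken to exclude it, so for members dim in NOD.B10 brightness and a strain difference such as leukocytes within NOD islets cannot be told apart.

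Within each array, Ins1 and Ins2 were lower in NOD relative to Gcg by log2 -1.63 (exact permutation p = 0.0152), a ratio that no array-wide factor moves, which argues against brightness as the whole cause. It argues in the same way against dilution of islet RNA by other cells, which would lower both hormones by 1 factor. The test by slide, which asked for no overlap within slides 2 and 3, did not decide. The difference was -1.60 within slide 2 and -1.88 within slide 3. NOD replicate 3 at -1.06 lay above all 6 NOD.B10 mice, so the value within slide 2 rests on NOD replicate 4 (-4.49). Within slide 3 the NOD mice (-3.33 and -3.25) lay below the NOD.B10 mice (-1.69 and -1.15). Slide alone cannot give that, though it rests on 2 mice per strain. The ratio shows unequal change of the hormone genes and not which of them changed. The unscaled signal of Gcg was 28080 in NOD and 12412 in NOD.B10, where bright probes rose by a median log2 of 1.65. Relative to the array, Gcg was lower after loess (log2 -1.19), in the net ratio and with the scanner's ratios. It was higher with Cy5 alone (0.97) and with median centring (0.77). Fewer beta cells, less insulin transcript per cell or more glucagon transcript in NOD may each give such a ratio, and were not tested.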

How the results depend on the processing

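The alternatives with slide as a fixed term, slides 2 and 3 with slide fixed, slide 2 alone, slide 3 alone, without slide 4, without genes of Cy5 under 1% of Cy3 and the net ratio were chosen after the result was seen. Reported values were 736 genes higher and 709 lower in NOD, 458 with a fitted change of at least 2-fold, 13 lists higher and 9 lower. Of 3852 comparisons of named genes with an alternative 3166 kept their direction and side of the threshold, 598 no longer passed, 18 newly passed and 70 reversed. Of 1030 comparisons of lists the numbers were 844, 108, 47 and 31. Repeats are among these: Aquantile after loess leaves the log ratios unchanged, so all 113 genes and 30 lists stayed the same. Slide 4 alone was read on the other scan day, so scan day as a fixed term repeats the differences found without slide 4. The authors' values largely repeat the scanner's processed ratios apart from centring. Values of genes and lists under another scaling are relative to its shift of all genes, and unless a reason is given the cause was not tested.

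Counts stayed within 1.5 times the reported ones with the filter on both channels, probes averaged or on their own, array weights, trend and robust fitting, slide as a random block, scan day as a fixed term and without slide 4. In these, 506 to 881 genes were higher and 523 to 804 lower, and where lists were tested 13 were higher and 9 to 12 lower. Lists were not tested with every probe on its own, and Adora1 gives no value under the filters on dim probes, which it fails. Camera with a preset correlation called 12 lists higher and 7 lower, and the exact permutation of mouse means 13 and 8.

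As a block, the replicate number gave 638 genes higher and 597 lower, 460 changed at least 2-fold, 13 lists higher and 7 lower. The numbers give no pairing of the mice: mice of the same number correlated at r -0.15 to 0.21 across genes, which are not independent replicates.

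Without background correction 14 lists were lower. With normexp offset 16 742 genes changed at least 2-fold, 14 lists were lower and the endocrine transcription factor mean turned to -0.036. With the scanner's processed ratios 331 genes were lower and 1280 changed at least 2-fold. There Ada turned to 0.46, Clic1 to -0.035, Foxa2 to -0.38, Neurod1 to -1.54, Postn to 0.77, Slc16a1 to 1.35 and the transcription factor mean to -1.32. With the authors' deposited values, 313 genes were lower and 1295 changed at least 2-fold, with Ada at 0.46, Clic1 at -0.035, Foxa2 at -0.37, Neurod1 at -1.54, Postn at 0.77, Slc16a1 at 1.35 and the transcription factor mean at -1.32.

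Median centring without loess gave 1980 genes higher and 0 lower in limma (2 lower at an unadjusted p under 0.05) and 22 lists higher and 0 lower in fry (0 at an unadjusted p under 0.05), since it leaves the trend with intensity in place and shifts the median of all genes to 0.44. Genes that turned were Adora1 (0.31), Adk (0.33), Bank1 (-0.011), Col1a1 (0.58), Fabp4 (0.058), Foxa2 (-0.39), Gcg (0.77), Il1b (-0.16), Il2rb (-0.15), Mbp (-0.0028), Ndufa9 (0.19), Ndufb3 (0.26) and Neurod1 (-0.41). Others were Pcsk2 (0.051), Pgam1 (0.33), Rbp4 (0.34), Sall4 (0.15), Sod2 (0.046) and Sst (0.52). List means that turned were alpha cell (0.13), delta and PP cell (0.25), endocrine transcription factors (-0.41), adenosine signalling (0.075), duct cell (0.15), antioxidant defence (0.11), oxidative phosphorylation (0.56) and glycolysis (0.69).

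Cy5 alone gave 247 genes lower, 148 changed at least 2-fold and 5 lists lower. It turned Cat (0.026), Foxa2 (-0.078), Gcg (0.97), Neurod1 (-0.40), Sall4 (0.51), Slc16a1 (0.17) and the alpha cell (0.15), transcription factor (-0.39) and glycolysis (0.17) means. Of the genes called there, 597 were also called higher and 137 lower in the reported values, and 15 were called in opposite directions. Without a filter 1392 genes were lower, more genes being tested. With Cy5 well above background on all 12 arrays, which leaves fewer genes, 162 were higher, 180 lower and 201 changed at least 2-fold, 3 lists were higher and the glycolysis mean was 0.010.

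With the share of spots well above background as a covariate, which follows the strains, 3 genes were higher, 0 lower and 3 changed at least 2-fold (limma, 153 and 134 at an unadjusted p under 0.05), and 0 lists were higher and 0 lower (fry, 6 and 0 at an unadjusted p under 0.05). Genes that turned were Ada (0.13), Btg2 (-0.19), Cat (0.15), Cd3d (-0.0068), Cd5 (-0.22), Cd74 (-0.29), Cdc20 (-0.21), Clic1 (-0.38), Cyc1 (0.053), Dnajb9 (0.037), Fabp4 (1.19), Flt1 (0.23) and Gc (0.11). Further ones were Gcg (0.59), Krt8 (0.046), Mbp (-0.036), Mcm7 (-0.25), Ndufa9 (0.021), Neurod1 (-0.082), Nkg7 (-0.14), Pip (0.076), Ptprb (0.34), Rbp4 (0.15), S100a9 (0.47), Sall4 (0.82) and Slc16a1 (0.45). Lists that turned were endocrine transcription factors (-0.32), duct cell (0.51), T cell (-0.088), antioxidant defence (0.0098), proliferation (-0.066) and glycolysis (0.55). With the acinar mean as a covariate 364 genes were higher and 311 lower.

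Slide as a fixed term gave 361 genes higher and 354 lower, of which 358 and 347 were among the reported calls, and turned the transcription factor (-0.015) and glycolysis (0.047) means. Slides 2 and 3 with slide fixed, which leaves 8 arrays, gave 235 higher, 169 lower, 264 changed at least 2-fold and 4 lists lower, with glycolysis at 0.047. Slide 2 alone, with 4 arrays, gave 38, 46 and 84 genes and 3 lists higher and 1 lower, with the endothelial mean at 0.019. Slide 3 alone gave 1, 1 and 2 genes and 1 list either way, with Foxa2 (-0.11), Ppy (0.18), Ptprb (0.055) and the transcription factor (-0.12) and glycolysis (0.29) means turned. Leaving out genes with Cy5 under 1% of Cy3, which most lower calls belong to, gave 268 lower, 300 changed at least 2-fold and 2 lists lower, with the delta and PP cell mean at 0.036. The net ratio, with 836 genes tested, gave 136 higher, 264 lower, 263 changed at least 2-fold, 3 lists higher and 5 lower, with Col1a1 at 0.32, Fabp4 at 0.058, Sod2 at 0.011, oxidative phosphorylation at 0.20 and glycolysis at 0.63. Camera with an estimated correlation called 0 lists higher and 0 lower (6 and 1 at an unadjusted p under 0.05).

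Leaving out 1 mouse gave 557 (without NOD replicate 2) to 842 (without NOD replicate 5) genes higher, 524 (without NOD replicate 2) to 763 (without NOD replicate 3) lower and 368 to 508 changed at least 2-fold. Lists higher numbered 13 to 14, and lists lower 6 (without NOD replicate 2 or 6) to 10 (without NOD replicate 3). Neurod1 ran from -0.060 without NOD replicate 3 to 0.19 without NOD replicate 4, and was -0.0025 without NOD.B10 replicate 6, and the transcription factor mean ran from -0.016 without NOD.B10 replicate 6 to 0.12. The reference channel gave 0 to 1 called genes, with 1 without NOD.B10 replicate 1 (limma, 194 at an unadjusted p under 0.05 with all mice).

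Adora1, at log2 -0.41 by its brightest probe, was 0.020 by the second probe and -0.23 by the third, which passed (adjusted p = 0.0319). It was 0.13 with scan day as a fixed term and without slide 4, and 0.041 with slide as a fixed term and on slides 2 and 3 alone. Leaving out 1 mouse it ran from -0.55 without NOD.B10 replicate 5 to -0.15 without NOD.B10 replicate 2. Signal over background limits Adora1 and most genes, since no array had more than 17.3% of its spots well above background in Cy5.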

Other observations

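The relation of the immune mean to array brightness and the choice of the net ratio and of the genes below were made after the result was seen.

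Whether mice with more immune signal have less insulin signal per glucagon signal was tested within each strain, in a family of 4 relations with those to brightness (exact permutation, Benjamini-Hochberg adjusted over the 4). Across the 6 NOD mice the insulin-to-glucagon ratio and the immune mean had a Spearman's rho of 0.0286 (exact p = 1, adjusted 1) and a Pearson's r of -0.34 (exact p = 0.553, adjusted 0.553). Without the 2 mice farthest from the median r was 0.73, so its sign rests on those mice. Across the 6 NOD.B10 mice rho was 0.314 (exact p = 0.564, adjusted 0.752) and r -0.41 (exact p = 0.486, adjusted 0.553), and again its sign rests on the 2 farthest mice (0.66 without them). Neither rho nor r can be told from 0 with 6 mice, and they differ in sign in both strains, so whether such a relation exists stays open.

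Arrays with brighter Cy5 might have higher immune means, which stays open. Across the 6 NOD mice rho was 0.829 (exact p = 0.0583, adjusted 0.233) and r 0.865 (exact p = 0.0292, adjusted 0.117), and r was 0.62 without the 2 farthest mice. Across the 6 NOD.B10 mice rho was 0.371 (exact p = 0.497, adjusted 0.752), r 0.362 (exact p = 0.465, adjusted 0.553) and r without the 2 farthest 0.80. With 6 mice, relations of this size do not pass once adjusted.

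In the net ratio of 836 genes bright on every array, given relative to its median change, several of the largest changes lay outside the gene lists. Higher in NOD were Srgn (log2 3.92), Shisa5 (3.58), Limd2 (3.33), Ifngr1 (2.66), C3 (2.53), Map3k1 (2.36), Serinc3 (2.19), Rpl12 (2.18), Cotl1 (2.17) and H2ac10 (2.17). Lower were Maob (-2.33), Rhobtb1 (-2.01), Slc2a5 (-1.95), Slc25a39 (-1.84), Akr1c19 (-1.83), Maged1 (-1.80), Cyb561 (-1.79), Prss53 (-1.78), Fkbp1b (-1.73) and Pomgnt2 (-1.73). Their limma adjusted p ran from 7.86e-07 to 0.0163. Of the lists in that measure, fry called MHC class I presentation (2.61, 3 of 3 genes, adjusted p = 4.62e-06), ribosomal proteins (1.67, 22 of 22, 5.41e-05) and other genes of the MHC region (0.99, 0.00355) higher. It called the beta cell (-1.42, 0.00112), endocrine granule (-1.37, 0.000343), autoantigen (-1.29, 0.000486), delta and PP cell (-0.76, 0.000486) and unfolded protein response (-0.63, 0.00885) lists lower. With camera and an estimated correlation the lowest adjusted p over these lists was 0.204.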
